A study of Drosophila melanogaster with 3 samples.

How the data were processed

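Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Drosophila melanogaster embryos of both sexes, collected 0 to 14 h after laying, from a transgenic line in which the protein CG15601 carries green fluorescent protein (GFP) at its C-terminal end. DNA bound to the tagged protein was recovered with an antibody against GFP, after sonication to fragments of 200 to 800 bp, per the labels. The series holds 3 samples, which the labels number as biological replicates 1, 2 and 3 of 1 group. There is no group without the tag among the samples.

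The authors deposited a peak list for each replicate, a list called on the 3 replicates pooled, and a list thresholded by the irreproducible discovery rate (IDR), a measure of how well the ranking of peaks repeats between replicates. Per the README listings of derived files, positions are on the dm6 assembly and the lists were called against the same control file. The peak caller and aligner are not given in the sources used here. Each deposited peak carries a signal value and a −log10 q-value from the authors' peak caller. Both values were used only to rank or describe peaks within a list, since signal is not scaled between lists. Read depth is unknown, because the lists hold no read counts, and the control track was not used here.

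Each of the 4 unthresholded lists held exactly 30000 peaks, so the number of peaks carries no information on binding. The IDR list held 6458 entries. All 6458 were also in the pooled list with the same position and signal, and exactly 6458 pooled peaks reached the lowest signal of the IDR list. IDR peaks are therefore the strongest pooled peaks, and a comparison of IDR peaks with the other pooled peaks compares strong with weak peaks. All IDR peaks shared the highest −log10 q of 4.16, so that column does not rank them. Of the IDR entries, 74 repeated the coordinates of another entry with a different summit, and the list merged to 6123 separate regions.

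Gene positions came from Ensembl release 115 (BDGP6.54, which has dm6 coordinates) and sequence from the RefSeq copy of genome release 6. No peak ran past the end of a chromosome in that sequence. The annotation, without transposable elements, gave 18164 genes, 13945 of them protein-coding, and 23998 transcription start sites (TSS) on the arms 2L, 2R, 3L, 3R, 4 and X. A summit was called promoter when it lay within 500 bp of a TSS. Other summits were placed, in this order, in a 5′ UTR, 3′ UTR, coding exon, other exon, intron or intergenic sequence.

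Replicate lists were compared by their strongest 6458 peaks, with 2 peaks matched when they overlapped by at least 50% of both. Chance overlap came from 1000 circular shifts of a list within each arm. Background peaks were the 21877 pooled peaks that overlapped no IDR peak, and 1665 pooled peaks that overlapped an IDR peak without being in the list were left out. Shares were compared with Fisher's exact test, two-sided, and adjusted by the Benjamini-Hochberg method over the 7 classes, the 28 gene lists, the 29 sequence words or the 8192 7-mers, with a threshold of 0.05. Intervals of shares are exact 95% binomial intervals and those of the odds are normal approximations on the log scale. All cover counting error over peaks or genes only. Peaks and genes are not independent biological replicates, so values of the 3 replicate lists are given for the promoter share, the annotation classes, the X chromosome and the gene lists that passed. Sequence words and 7-mers were not tested in the replicate lists, except for the strongest 500 peaks in the closing section. The X chromosome was compared with arms 2L to 3R by an exact binomial test on sequence length. Sequence was read within 50 bp of the summit on both strands, and a 7-mer was called enriched with an adjusted p under 0.05 and a share ratio of at least 1.5.

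The main tests, gene lists and sequence words, the alternatives listed below and the rule for naming genes were fixed before the data were examined. Alternatives added later are named as such, and the values by range of ranks, for the 100 strongest peaks, of offsets from the TSS, of GC content and of TSS on both strands were also chosen afterwards. That rule takes the 20 strongest promoter peaks, the 5 strongest other peaks, CG15601 and, for each list that passed, the 3 bound genes with the strongest peaks and any unbound genes where there were 5 or fewer. It also takes the 3 words with the highest and the 3 with the lowest ratio among those that passed, and the 5 7-mers with the lowest p. Some older gene symbols were replaced by current ones afterwards, by name only. Not every gene that the rule takes is named here. Other genes named here were chosen after their values were seen.

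The code was tested on simulated data. With nothing planted, 0 of 8192 7-mers and 0 of 29 words were called among the real background windows. With 10 7-mers planted in 3% of windows, all 10 were called, together with 62 others that each shared 4 bases in a row with a planted one. Of gene lists raised to 3 times the odds, 87 of 100 were called, and 2 of 460 unchanged lists. Peaks moved by 100 bp matched in 2000 of 2000 cases, and peaks moved by 300 bp in 27 of 2000. The alternatives covered the overlap rule, the number of peaks per replicate, the TSS window, the sequence window, the background, the stronger 3229 IDR peaks and leaving out each replicate in turn. For tests on IDR peaks, leaving out a replicate kept only the peaks matched in both others. This left 3558, 3203 and 3208 peaks without replicates 1, 2 and 3. The IDR list, its signal and the background still came from all 3 replicates, so a lost call can reflect fewer peaks. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0.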

Results

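Binding of GFP-tagged CG15601 was mapped by ChIP-seq in whole embryos collected 0 to 14 h after laying. The data were peak lists from 3 biological replicates of 1 group, a pooled list, and a list of 6458 peaks that passed the IDR threshold. The series title names transcription factor ChIP-seq, and the question addressed here is where the tagged protein was found in the genome and how far the 3 replicates gave the same places. Peaks had a median width of 430 bp in the pooled list and of 404, 420 and 410 bp in replicates 1, 2 and 3.

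The strongest sites were the same in every replicate. The strongest peak of all (chromosome 2R, 7477447 to 7479407, dm6) lay in intergenic sequence 1608 bp from the TSS of Aldh-III, an aldehyde dehydrogenase gene, and ranked 2, 1 and 1 in replicates 1, 2 and 3. The next were at the promoters of CG46339 (3R, 26915433 to 26917010), the non-coding RNA gene lncRNA:CR45717 (2L, 1142361 to 1143428), the kinase gene Nuak (3R, 10263548 to 10264538) and btsz, which encodes the synaptotagmin-like protein Bitesize (3R, 14853444 to 14854451). Each of these 4 ranked between 1 and 6 in all replicates. The gene shn, which encodes the zinc finger protein Schnurri of the Dpp pathway, held 2 of the 10 strongest peaks, with rank 6 at its promoter and rank 9 in an intron, 2588 bp from the nearest TSS. Of the 100 strongest IDR peaks, 98 overlapped a peak among the strongest 200 of every replicate list.

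Promoters among the 20 strongest promoter peaks also included Socs16D, a suppressor of cytokine signalling gene, with rank 8 in the IDR list, and CG14100 with rank 10. Lapsyn, which encodes a leucine-rich repeat protein, ranked 11, and Con, which encodes the cell adhesion protein Connectin, ranked 12. Reph ranked 13 and CG17075 ranked 14. RpS20, a ribosomal protein gene, shared the peak of rank 15 with CG17271 on the opposite strand. On the X chromosome, CG15646 and its neighbour CG12708 had ranks 17 and 22, with summits at 15671287 and 15675425 on the same chromosome as CG15601, which starts at 15710647. CG10254, CG31676 and CG43373 had ranks 21, 24 and 25. GLaz, which encodes the lipocalin Glial Lazarillo, shared the peak of rank 26 with Spt-I, a serine palmitoyltransferase gene, and Cep135, a centriole gene, had rank 28. The other strong peaks away from a TSS were intergenic, at rank 7 (1941 bp from CG6465), rank 18 (1865 bp from the rhodopsin gene Rh5) and rank 19 (1578 bp from the glutamate transporter gene Eaat2).

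How often a peak repeated depended on its rank and on how much of the other list was searched. In the full list of another replicate, 95.1% to 99.0% of peaks ranked 1 to 500 were matched, 72.1% to 72.5% of those ranked 1001 to 2000, 78.6% to 88.5% of those ranked 4001 to 6458, and 29.9% to 39.0% of those ranked 15001 to 30000. Among the strongest 6458 peaks only, the share was 94.9% to 98.9% for ranks 1 to 500 and 42.3% to 50.8% for ranks 4001 to 6458, where many matches lay beyond rank 6458. Over the strongest 6458 peaks, replicates 1 and 2 shared 60.3%, replicates 1 and 3 shared 60.4%, and replicates 2 and 3 shared 65.8% (mean 62.1% ± 3.14, SD, 3 pairs). The highest value in 1000 circular shifts was 2.21%, a permutation p of 0.001 for each pair, the smallest that 1000 shifts can give. Signal ranked alike in pairs of replicates, with a Spearman correlation of 0.655, 0.630 and 0.669 for replicates 1 and 2, 1 and 3, and 2 and 3, across 4637, 4654 and 4990 IDR peaks, which are not independent replicates.

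**Figure D1:**
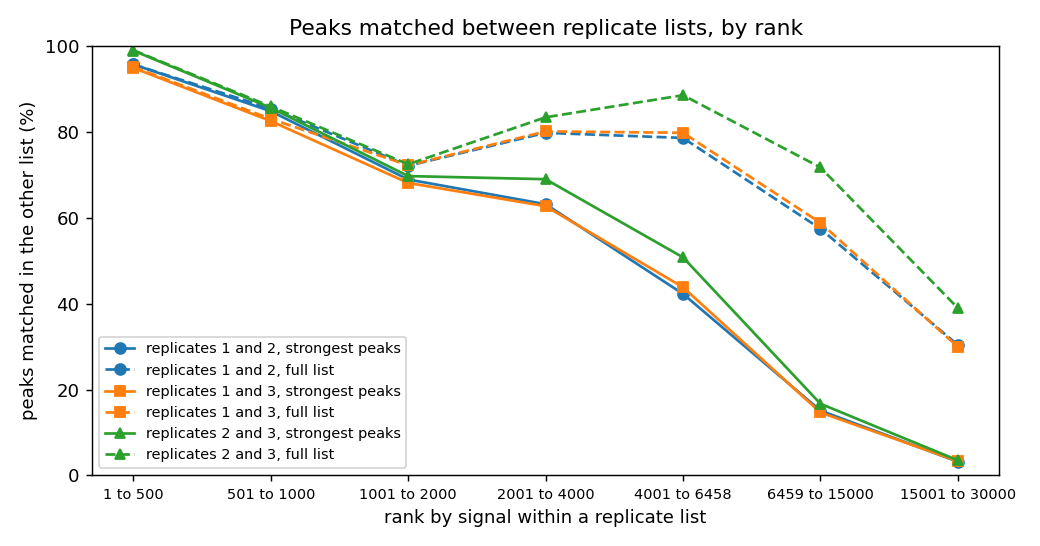
Share of peaks (%, y axis) in each range of ranks by signal (x axis) with a match in the other list, mean of both directions, for each pair of replicates. Solid lines search the strongest 6458 peaks of the other list and dashed lines its full 30000. For ranks 4001 to 6458 the pairs lay at 42.3% to 50.8% and at 78.6% to 88.5%.

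In the IDR list, 2669 of 6458 peaks (41.3%, 95% interval 40.1 to 42.5) were matched among the strongest 6458 peaks of all 3 replicates. A further 30.4% were matched in exactly 2 replicates, 17.7% in 1, and 10.6% in none. By replicate the share was 63.1%, 70.0% and 69.4% (67.5% ± 3.83, SD, n = 3). These shares depended on the matching rule. With every peak of the replicate lists admitted, 68.8% were found in all 3, and with the strongest 3229 only, 22.7%. With every peak and any overlap of at least 1 bp, a rule chosen after the data were seen, the share was 92.9%.

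Promoters held a larger share of the IDR peaks than of the weaker peaks or of the genome. Of the 6458 summits, 3267 (50.6%, 95% interval 49.4 to 51.8) were within 500 bp of a TSS, against 5066 of 21877 background peaks (23.2%), odds of 3.40 (95% interval 3.21 to 3.60). Such positions made up 13.6% of the genome, so that promoters held 3.72 times the share of random placements (permutation p of 0.001, the smallest that 1000 placements can give). In the replicate lists, promoter peaks made up 45.0%, 51.4% and 55.1% of the strongest 6458 (50.5% ± 5.12, SD, n = 3), with odds of 3.03 ± 0.318 against the weaker peaks of the same list (range over lists 2.72 to 3.36). Promoter summits lay a median of 91 bp upstream of the nearest TSS, with 78.1% upstream of it. The share was 41.7% within 250 bp of a TSS and 47.9% with protein-coding genes only.

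Coding exons and 3′ UTRs held fewer of the IDR summits than of the background. Coding exons held 13 summits, 0.201% against 2.14% (odds 0.0923, adjusted exact p = 1.39e-36), and 3′ UTRs 0.821% against 4.02% (odds 0.197, adjusted exact p = 4.97e-47), with odds of 0.127 for 3′ UTRs without replicate 3. Introns held 32.7% against 46.2% (odds 0.566, adjusted exact p = 8.40e-84), intergenic sequence 14.1% against 22.4% (odds 0.571, adjusted exact p = 1.08e-49) and 5′ UTRs 0.573% against 1.07% (adjusted exact p = 1.76e-04), while other exons did not pass (0.975% against 1.01%, adjusted exact p = 0.887). In replicates 1, 2 and 3 taken singly, introns held 36.1%, 32.7% and 29.4% of the strongest 6458 summits (32.7% ± 3.36, SD, n = 3) and intergenic sequence 14.2% ± 1.91. Coding exons held 0.181% ± 0.0179, 3′ UTRs 0.898% ± 0.0410, 5′ UTRs 0.650% ± 0.124 and other exons 0.919% ± 0.0447. The shares sum to 100%, so the larger promoter share lowers all others. Among summits outside promoters only, a comparison chosen after the data were seen, coding exons (odds 0.143, adjusted exact p = 5.56e-21) and 3′ UTRs (0.306, adjusted exact p = 7.17e-22) were still lower. Introns were then higher (66.2% against 60.2%, odds 1.30, adjusted exact p = 2.07e-10), as were other exons (odds 1.52, adjusted exact p = 0.00790), and intergenic sequence (28.6% against 29.1%, adjusted exact p = 0.566) and 5′ UTRs (odds 0.828, adjusted exact p = 0.381) did not pass. Distal sites were still common, with 974 IDR summits (15.1%) farther than 5000 bp from any TSS.

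**Figure D2:**
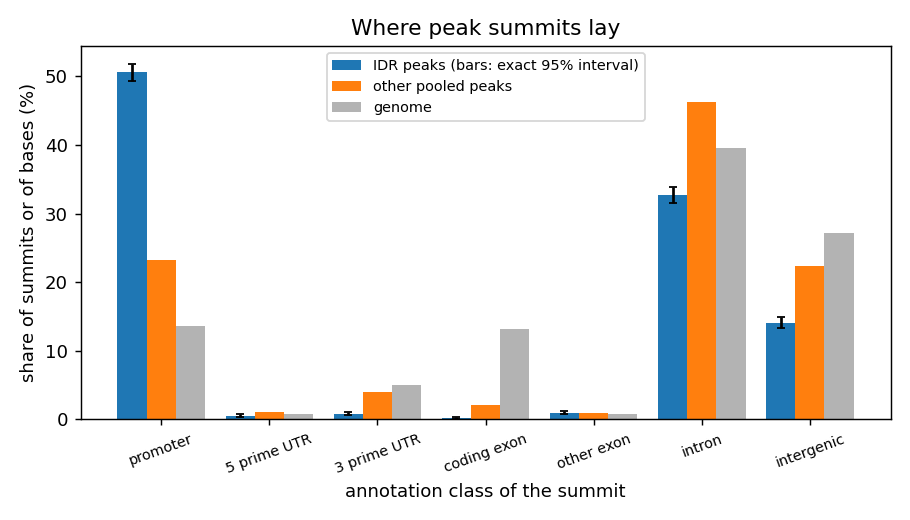
Share of summits (%, y axis) in each annotation class (x axis) for IDR peaks, with exact 95% intervals, and for the other pooled peaks, beside the share of genome bases in the class. Promoters held 50.6% of IDR summits, 23.2% of other summits and 13.6% of the genome.

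Promoter peaks were more frequent among the strongest sites. Of the 100 strongest IDR peaks, 69 were at promoters (95% interval 59.0% to 77.9%), against 49.7% of those ranked 1001 to 6458. Between the strongest 1292 and the weakest 1291 IDR peaks the share fell from 54.3% to 47.9% (odds 1.29, Fisher's exact p = 0.00125). This difference depended on the window and the replicate. With 250 bp around the TSS the odds were 1.05 (exact p = 0.523), and within the list of replicate 2 they were 1.05 (p = 0.582), against 1.83 in replicate 1 and 1.32 in replicate 3.

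The X chromosome carried fewer IDR peaks per base than the large autosomal arms. There were 44.6 IDR peaks per Mb on X against 54.1, 47.5, 51.3 and 46.0 on 2L, 2R, 3L and 3R, an X to autosome ratio of 0.903 (exact binomial p = 0.00227). Background peaks went the other way, with a ratio of 1.10 (exact p = 1.28e-07), and the odds of an IDR peak on X against the background were 0.823 (p = 2.23e-07). The replicate lists gave ratios of 0.939, 0.895 and 0.850 (0.895 ± 0.0445, SD, n = 3), with an exact p of 0.0581 in replicate 1. Chromosome 4 held 27 IDR peaks, 20.3 per Mb. No list held a peak on Y, for which mapping of repeated sequence was not assessed here. Gene density also differed, at 120 genes per Mb on X and 154, 148, 126 and 135 on 2L, 2R, 3L and 3R. The binomial test took the expected share from sequence length alone. Neither gene density nor the copy number of X in embryos of both sexes was taken into account, so the cause of the lower ratio was not tested.

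Among 29 fixed sequence words, the DRE, CTCF and M1BP words had the highest ratios under the IDR peaks. The DRE, the site of the transcription factor Dref, was within 50 bp of 155 summits (2.40%) against 0.772% of background summits, a ratio of 3.11 (adjusted exact p = 2.85e-22). The CTCF core had a ratio of 3.04, with 26 peaks (0.403% against 0.133%, adjusted exact p = 2.00e-04), and the core of Ohler motif 1, bound by M1BP, a ratio of 2.52 (1.63% against 0.644%, adjusted exact p = 1.86e-11). Ohler motif 6 (ratio 1.85), the Forkhead (1.62), BEAF-32 (1.41), homeodomain (1.34), TATA (1.33) and GATA (1.18) words were also enriched. Among the words that passed, the lowest ratios were those of the CA repeat (ratio 0.683, adjusted exact p = 2.00e-04), the GAGA repeat of Trl and Clamp (0.724, adjusted exact p = 0.00941) and the Pho core (0.783, adjusted exact p = 3.72e-12). The GAGA core and poly(A) words were also depleted, at ratios of 0.819 and 0.836. In all, 9 of 29 words were enriched and 5 depleted, and neither Zelda word differed (adjusted exact p = 0.450 for the TAGteam word and 0.625 for the core). Ohler motif 6 did not pass on the fewer peaks kept without replicate 1 (ratio 1.97), 2 (1.80) or 3 (1.42). The GATA word (1.14), CA repeat (0.754) and GAGA repeat (0.736) did not pass without replicate 1, nor poly(A) (0.872) without replicate 3. The GAGA repeat had a ratio of 0.481 without replicate 2.

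IDR summits lay in sequence with 34.7% G and C, against 38.9% around background summits, and the ratios of several words changed when this was matched. Against a background matched on GC content, an alternative chosen after the data were seen, the CTCF core (ratio 5.14), DRE (4.18), M1BP (3.46), BEAF-32 (1.57) and Forkhead (1.38) words stayed enriched and poly(A) depleted (0.693). The TATA (0.965), homeodomain (1.07), GATA (1.01), Ohler motif 6 (1.32), Pho (0.960), CA repeat (0.868), GAGA core (1.06) and GAGA repeat (1.10) words did not pass. The matched background held 3829 windows, and the words were not tested against a random background of that size. A lost call can therefore also reflect fewer windows. The ratios differed between promoter peaks and peaks away from promoters. Among promoter peaks alone the DRE word had a ratio of 1.83 (4.59% against 2.51%, adjusted exact p = 1.95e-06) and M1BP 1.42 (adjusted exact p = 0.0344), and the CTCF core (1.55, adjusted exact p = 0.583) and Forkhead (1.17, adjusted exact p = 0.387) did not pass. Away from promoters the CTCF core (4.39, adjusted exact p = 3.01e-04) and Forkhead (2.01, adjusted exact p = 6.73e-14) words were enriched, and the DRE (0.627, adjusted exact p = 0.496) and M1BP (0.823, adjusted exact p = 0.883) words did not pass. The difference in ratio between promoter and other peaks was not itself tested. Neither comparison was matched on GC content. It was 35.5% against 40.1% in the background at promoters, and 33.9% against 38.5% away from them. In the strongest 500 peaks, a set chosen after the data were seen, only the TATA (1.52), homeodomain (1.58) and Forkhead (1.81) words were enriched against all background windows. The CTCF core (4.53, 3 peaks, adjusted exact p = 0.171) and the DRE (0.518, 2 peaks, adjusted exact p = 0.741) did not pass on few peaks. The strongest 500 peaks had 32.6% G and C, and their words were not tested against a GC-matched background.

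**Figure D3:**
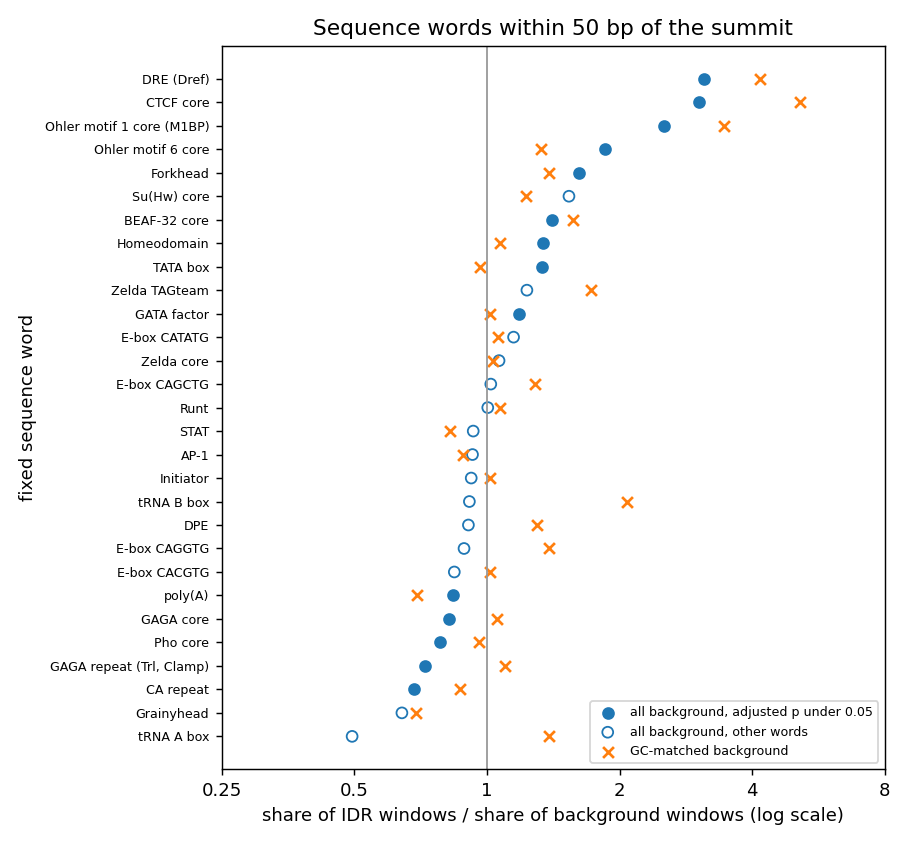
Ratio (x axis, log scale) of the share of IDR windows to the share of background windows with each of 29 sequence words (y axis), against all background windows (circles, filled where the adjusted exact p was under 0.05) and against a GC-matched background (crosses). The DRE, CTCF core and M1BP words lay above 2.5 with both backgrounds.

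Of 8192 7-mers, 212 were enriched. The 5 with the smallest p were ATCGATA (5.09% of IDR windows against 2.23%), TAAAATA (12.4% against 7.77%), TAAATAA (13.2% against 8.54%), CTATCGA (3.55% against 1.34%) and TTTAAAA (12.5% against 8.06%), with adjusted exact p from 8.47e-26 to 1.11e-22. Against the GC-matched background 34 were enriched, 25 of them among the 212, whereas a random background of the same size gave 192. With IDR peaks matched in both remaining replicates, 246, 351 and 316 were enriched without replicates 1, 2 and 3.

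Genes of protein synthesis and turnover had an IDR summit at their promoters far more often than other genes. A gene with such a summit is called bound, although binding of the antibody without the tag stays open here. Of the 85 cytoplasmic ribosomal protein genes, 74 (87.1%, 95% interval 78.0 to 93.4) had an IDR summit within 500 bp of a TSS, against 22.2% of other genes (odds 23.5, adjusted exact p = 3.07e-35). RpS20 had the strongest of these peaks (rank 15), followed by RpL23A (rank 323) and RpL7 (rank 342). Of the mitochondrial ribosomal protein genes 36 of 73 were bound (odds 3.37, adjusted exact p = 4.42e-06), led by mRpS10, mRpL41 and mRpS23 with ranks 49, 59 and 74. Proteasome subunit genes were bound in 18 of 32 cases (odds 4.43, adjusted exact p = 1.48e-04), with Rpn13, Rpn9 and Rpn11 the strongest. Translation factor genes were bound in 23 of 51 (odds 2.83, adjusted exact p = 9.55e-04), led by eIF4EHP (rank 78), eIF6 and eEF1gamma, and spliceosome and SR protein genes in 15 of 28 (odds 3.98, adjusted exact p = 9.55e-04), led by U2af50 and SC35. With 1 replicate left out, that is with only the IDR peaks matched in both others, fewer genes were bound. Without replicates 1, 2 and 3 in turn the odds were 7.06, 6.76 and 8.91 for the cytoplasmic ribosomal protein genes, which passed each time. They were 3.70, 3.75 and 3.22 for the mitochondrial ribosomal protein genes, which also passed each time, and 1.97, 1.65 and 2.48 for the proteasome genes and 1.62, 1.97 and 1.59 for the translation factor genes, which passed in none. The spliceosome list did not pass without replicate 2 (odds 2.38) or replicate 3 (1.61). With the stronger 3229 IDR peaks the proteasome (odds 1.94) and spliceosome (2.31) lists did not pass. In the lists of replicates 1, 2 and 3 taken singly, the odds were 22.4, 23.6 and 10.1 for the cytoplasmic and 2.95, 3.77 and 4.68 for the mitochondrial ribosomal protein genes. They were 1.81, 2.37 and 3.48 for the proteasome, 2.37, 1.89 and 2.96 for the translation factor and 1.89, 3.46 and 4.75 for the spliceosome list. All passed except the proteasome and spliceosome lists in replicate 1 and the translation factor list in replicate 2.

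Genes of chromatin and the cell cycle were also bound more often. Of 17 genes of insulator and promoter-binding factors 12 were bound (odds 8.27, adjusted exact p = 1.48e-04), with Chro (rank 67), Cp190 (rank 150) and Dref (rank 634) the strongest and Ibf1, Ibf2, dwg, su(Hw) and zld unbound. Polycomb group genes were bound in 10 of 19 cases (odds 3.83, adjusted exact p = 0.0103), led by ph-p (rank 52), E(z) (rank 271) and Su(z)12. Heat shock genes were bound in 9 of 17 (odds 3.87, adjusted exact p = 0.0141), led by Hsp27, Hsp83 and Hsp26, and cell cycle and DNA replication genes in 14 of 32 (odds 2.68, adjusted exact p = 0.0195), led by RnrS, E2f1 and Cdk1. The cell cycle list did not pass without replicate 1 (odds 2.31) or replicate 3 (2.48), and the Polycomb list did not pass without replicate 2 (2.55) or replicate 3 (1.98). The odds of the insulator list were 5.20 without replicate 3. With the stronger 3229 IDR peaks the Polycomb (1.30) and cell cycle (2.31) lists did not pass. Against protein-coding genes only, the heat shock (3.09, adjusted exact p = 0.0575) and cell cycle (2.14, adjusted exact p = 0.0933) lists did not pass. In the lists of replicates 1, 2 and 3 taken singly all 4 passed, with odds of 7.31, 6.34 and 7.37 for the insulator, 3.58, 3.84 and 5.26 for the Polycomb, 4.48, 3.89 and 3.45 for the heat shock and 3.99, 2.37 and 5.12 for the cell cycle list.

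Bound less often than other genes were tRNA genes, with 34 of 295 bound (odds 0.443, adjusted exact p = 8.18e-06), led by tRNA:Tyr-GTA-1-8, tRNA:Val-AAC-2-4 and tRNA:Arg-CCT-1-2. Bound means here an IDR summit at the promoter, so genes with only a weaker pooled peak count as unbound. These values therefore do not show that tRNA genes lacked peaks. The tRNA odds were 0.273 without replicate 2 and 0.284 without replicate 3. In the single lists of replicates 1, 2 and 3 they were 0.270, 0.617 and 0.462. Odorant receptor genes were bound in 0 of 59 cases (95% upper bound 6.06%, adjusted exact p = 3.71e-06), and gustatory receptor genes in 2 of 60, Gr63a and Gr97a (odds 0.118, adjusted exact p = 2.38e-04). In the single lists of replicates 1, 2 and 3 the gustatory odds were 0.0671, 0.0583 and 0.105, and no odorant receptor or histone gene was bound. None of 111 replication-dependent histone genes was bound (adjusted exact p = 1.31e-11), but these are near-identical repeated copies to which short reads may not map uniquely, so that value is uncertain.

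None of the lists of developmental regulators passed with the 500 bp window. Hox genes were bound in 0 of 8 cases (adjusted exact p = 0.394), maternal and gap genes in 2 of 13, pair-rule genes in 2 of 9, segment polarity genes in 4 of 13 and dorsoventral genes in 5 of 17. Neural genes were bound in 3 of 22 cases, muscle genes in 4 of 18, hemocyte genes in 2 of 11, endoderm genes in 3 of 8 and epidermal genes in 1 of 12. Germ plasm genes were bound in 5 of 11 (adjusted exact p = 0.158), Enhancer of split and Notch pathway genes in 6 of 16 (adjusted exact p = 0.394), snRNA genes in 8 of 32, dosage compensation genes in 2 of 7 and chorion and yolk genes in 1 of 13. Intervals of these small lists were wide, from 0% to 36.9% for the Hox genes. Some passed under an alternative: neural genes were bound less often within 250 bp (0 of 22, adjusted exact p = 0.0461). Germ plasm genes were bound more often in the list of replicate 1 (odds 4.78, adjusted exact p = 0.0278) and endoderm genes in that of replicate 2 (5.76, adjusted exact p = 0.0412).

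Among genes that had any pooled peak at the promoter, only the cytoplasmic ribosomal protein genes stayed enriched (90.2% bound against 51.4%, odds 8.74, adjusted exact p = 1.43e-12) and only the tRNA genes depleted (18.6% against 52.6%, adjusted exact p = 2.34e-19). The other 8 enriched lists did not pass, with adjusted exact p from 0.142 to 0.923 on fewer genes. The odds were 4.19 for the heat shock list (3.87 among all genes) and 2.38 for the translation factor list (2.83). They were lower than among all genes for the insulator (3.73), proteasome (2.40), spliceosome (2.00), mitochondrial ribosomal protein (1.87), Polycomb (1.55) and cell cycle (1.30) lists.

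**Figure D4:**
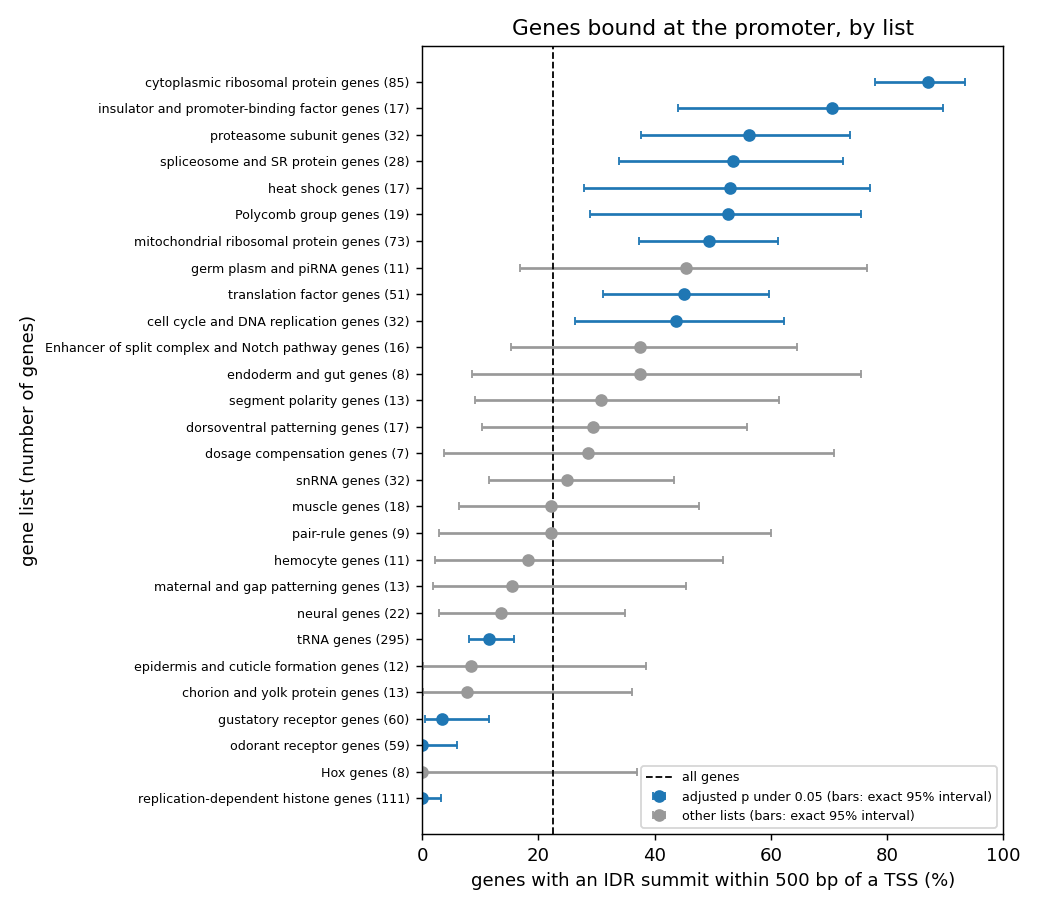
Share of genes (%, x axis) with an IDR summit within 500 bp of a TSS in each of 28 gene lists (y axis, number of genes in brackets), with exact 95% intervals. The dashed line marks all genes, at 22.5%, and the cytoplasmic ribosomal protein genes lie highest, at 87.1%.

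The gene of the tagged protein, CG15601 (FBgn0030673, X, 15710647 to 15712309, plus strand), had 4 IDR summits within 5000 bp, of ranks 1995, 2366, 2833 and 6005. Summits at 15710695 and 15710900 lay inside the gene near its start, 1 at 15709765 lay upstream of the gene, and 1 at 15712584 lay past its end. The IDR peaks inside the gene overlapped each other. The number of peaks in this interval was 1, 6 and 7 in replicates 1, 2 and 3, and the replicate 1 peak lay upstream of the gene. The line carries a transgene of CG15601, and whether its copies add to the peaks here was not tested.

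**Figure D5:**
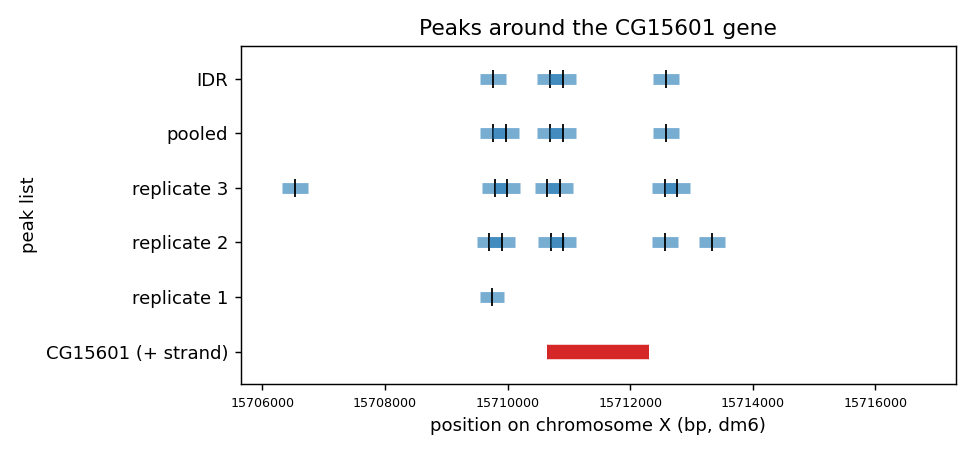
Peaks (blue bars, with summits as black ticks) of each list (y axis) within 5000 bp of the CG15601 gene (red bar) on chromosome X (x axis, bp, dm6). The IDR list has 4 summits here and replicate 1 has 1 peak.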

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

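The GC-matched background, the strongest 500 peaks, peaks away from promoters, 7-mers in promoter peaks, merged regions, summits outside promoters and the 1 bp rule with every peak were chosen after the data were seen. Of 61 alternatives of the main results fixed in advance, 45 stayed on the same side of the threshold or, for a number of calls, within 1.5 times it. Another 9 moved the value, 3 gave more calls and 4 weakened the result. The 45 include the replicate overlap without each replicate, which only repeats the values of the main pairs. The replicate overlap and promoter enrichment held in direction and call under each alternative, as did the X to autosome ratio except in the list of replicate 1 (0.939, exact p = 0.0581), with promoter odds of 3.43 to 4.24 without each replicate. The share of IDR peaks found in all replicates was 62.6% at 1 bp, 54.2% by summits within 100 bp, 68.8% with every peak, 22.7% with the strongest 3229, 92.9% with every peak at 1 bp, and 49.6% to 55.1% without each replicate, where fewer lists had to match. The promoter odds by strength were 1.05 at 250 bp. The Spearman correlation of signal averaged 0.612 at 1 bp. Leaving out each replicate leaves 1 pair, so it only repeats the main values of 0.630 to 0.669.

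Enriched 7-mers numbered 354 in the stronger 3229 peaks, 139 within 100 bp, 930 against flanks, 34 against GC-matched windows, 77 in the strongest 500 peaks and 246 to 351 without each replicate. Of the 29 words, 14 were called in the main test, 10 without replicate 1, 10 in promoter peaks alone, 8 away from promoters, 6 against GC-matched windows and 4 in the strongest 500 peaks, where fewer peaks were tested. Ratios turned for the GAGA repeat within 100 bp (1.05) and against GC-matched windows (1.10), poly(A) against flanks (1.21), and the GAGA core (1.06) and TATA word (0.965) against GC-matched windows. They turned away from promoters for M1BP (0.823, 5 peaks), DRE (0.627, 5 peaks) and BEAF-32 (0.989), and in the strongest 500 peaks for DRE (0.518, 2 peaks) and Ohler motif 6 (0). Of these turned word ratios only that of poly(A) against flanks passed (adjusted exact p = 0.00234). The others are lost calls and do not show a change of direction. Gene lists called numbered 2 among genes with a pooled promoter peak, where the gustatory odds were 1.86, 9 with the stronger 3229 peaks and 8 to 10 without each replicate, against 13. Outside promoters the class odds turned for introns (1.30) and other exons (1.52), because the promoter share no longer lowers them. Uncalled other-exon odds were 1.01 in merged regions and 0.867 to 1.01 without each replicate. The cause was not tested where none is named. No paired analysis was possible because there is 1 group. Depth is unknown, so it could not be weighed.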

Other observations

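IDR promoter peaks were often near start sites of both strands. Of the 3267 IDR promoter peaks, 1183 (36.2%, 95% interval 34.6 to 37.9) had a TSS on both strands within 500 bp, against 759 of 5066 background promoter peaks (15%), odds of 3.22 (Fisher's exact p = 8.69e-109). The share was 35.8% ± 0.747 (SD, n = 3) for the strongest 6458 peaks of the replicate lists and 17.8% ± 2.41 for their weaker peaks, with odds of 3.21, 2.17 and 2.50. By class of gene, 3728 of 13945 protein-coding genes were bound (26.7%), 296 of 3261 non-coding RNA genes (9.08%) and 17 of 269 snoRNA genes (6.32%).

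Peaks of the pooled list were crowded in a few regions. The densest 80 kb window, on 2L from 14470001 to 14550000 with the gene noc, held 95 pooled peaks and 14 TSS, against a median of 16 pooled peaks over all windows. It held 85, 84 and 83 peaks in replicates 1, 2 and 3. Windows on 3L from 11350001 (94 pooled peaks, 7 TSS) and on 3R from 4960001 with the gene plh (86 pooled peaks, 7 TSS) followed. The 80 kb around CG15601 (X, 15671478 to 15751477) held 34 pooled peaks, more than in 79.7% of windows of a similar number of TSS. Replicate 1 had 13 peaks there, more than in 20% of such windows. The strong peak at CG12708 (rank 22) lay in this window, and that at CG15646 (rank 17) lay just outside it. Whether strong peaks gather around CG15601 beyond chance, or copies of the transgene add to the peaks there, was not tested. These values were chosen after they were seen.

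All tests in the following paragraphs, and the limits by which they were read, were chosen after the results were seen, and the design names no group that would allow a biological explanation to be tested.

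Base composition is a candidate explanation for many of the enriched 7-mers, since fewer were called with a GC-matched background (34) than with a random one of equal size (192). With a GC-matched background of 3829 windows, 0 of the 34 called 7-mers were made of A and T only, against 18 of 192 with a random background of equal size, so these 7-mers may reflect A and T rich sequence under the peaks. For 7-mers holding ATCGA, the core of the DRE, 7 were called with the GC-matched background and 8 with the random one, which argues against GC content as their cause. The GC-matched windows were not matched on promoter position, which also differed. Among promoter peaks alone 5 such 7-mers were called, and away from promoters 0, so the larger promoter share stays open as part of the cause. Whether Dref itself or the tagged protein meets the ATCGA sites also stays open.

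In the strongest 500 peaks, 7-mers holding TTGAA or its complement stood out, such as CTTTCAA (9% against 3.07% of GC-matched windows). Of 14 such 7-mers called against all background windows, 71.4% were still called with 3549 GC-matched windows. This argues against GC content as the whole cause for those still called. The 29 of A and T only fell to 0, but no random background of equal size was tested here. Their loss can therefore also reflect fewer windows. Many of the TTGAA 7-mers overlap one another, so they are not separate observations. On 2L, 3L and X, 7 words were found, 4 of them called again singly on 2R, 3R and 4. Of the strongest 500 peaks, 226 lay on 2R, 3R and 4. In these the words had odds of 2.59 (95% interval 1.80 to 3.72) against 760 GC-matched windows. The TTGAA core had been picked with those arms in view, and the 6 other words found were left out. The odds are therefore not an independent test and cannot exclude chance. On those arms the excess lay mainly in ranks 1 to 100 (52% of 50 peaks). Ranks 101 to 500 (19.9%) were similar to 501 to 1000 (20.2%) and 1001 to 2000 (18.3%), against 12.5% of GC-matched windows. To ask whether 1 library was the cause, a first test counted TTGAA 7-mers called in each replicate list. It gave 2, 5 and 12, with 1 of 10 words called in all 3, and decided nothing. After those counts were seen it was replaced, as they depend on background size, by the odds on the same arms. The lowest of these odds was 1.95 (1.34 to 2.83). The words came from the pooled peaks, and 95.1% to 99% of peaks ranked 1 to 500 in a replicate matched another replicate. The strongest sites were thus shared, but the odds mostly read the same sites again. They are not a separate test of the words and cannot exclude 1 library. A sequence recognised by the tagged protein or a partner may account for the TTGAA excess, as an untested hypothesis, and binding of the antibody without the tag stays open because no untagged sample is used here.

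The enriched gene lists could reflect promoters that give a peak of any strength, such as accessible or highly transcribed ones. Among genes with any pooled promoter peak, the odds of an IDR peak were 8.90 (95% interval 4.29 to 18.5) for the cytoplasmic ribosomal protein genes against the 7619 genes in none of the enriched lists, which argues against the presence of a peak of any strength as the whole cause for them. This restates the comparison given above, with the same ribosomal protein genes and a narrower comparison group. It is not separate evidence. For the other 8 enriched lists, of which none passed in that comparison on fewer genes, this explanation is neither supported nor excluded and stays open. Peak strength that follows transcription or accessibility stays open for all, since neither was measured here. Binding of the antibody without the tag also stays open for the gene lists and the promoter share, because no untagged sample was used.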
